A study of Mus musculus with 24 samples.

How the data were processed

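Total RNA from 24 mouse cortical tumours was extracted with Trizol and labelled with biotin by the standard Affymetrix protocol, per the labels' protocols, and each tumour was measured on its own single-colour array. The deposited table holds 45141 probe sets, with 1 log2 expression value per probe set and tumour. That the deposited values are log2 intensities already brought to a common scale was read from the values themselves, which lie between 2.40 and 13.85 with a lower quartile of 3.51 to 3.60 and an upper quartile of 7.58 to 7.69 in every array. Partek version 6.6 was used, per the submitters' processing notes; the sources used here do not name the background correction, the normalization or the summarisation of probes. A normalization that equalises the arrays would hide a change shared by most genes. Single probes and background values are not in the table, so signal over background was not assessed for any single value.

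Groups were taken from the class gene label (RAB3A, BC74C or ZNF668) and from the tumour label (ependymoma, HGG, TUMOR or UNKNOWN). Replicate numbers follow the order of deposit. Titles begin with elw in 18 tumours and with mmr in 6. Since this may mark a batch, it was used as a block and to divide the tumours in alternatives. The mmr titles belong to 2 RAB3A, 1 BC74C and 3 ZNF668 tumours, so any comparison with BC74C within mmr rests on 1 BC74C tumour.

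The 104 control probe sets were left out. Of the others, 28898 carry 1 gene symbol, 551 several and 15588 none. Each of 17097 genes was represented by its single-symbol probe set with the highest mean, and genes whose probe set mean lay below the 30th percentile of all probe sets (a log2 value of 3.76) were left out, leaving 13218. Gene names come from the platform's annotation, matched by Entrez identifier to a RefSeq table of assembly GRCm38.p6 for 28689 probe sets; no coordinates were used.

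Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. RAB3A minus ZNF668, BC74C minus ZNF668 and RAB3A minus BC74C came from a single model of the 24 tumours. HGG minus ependymoma came from the 15 tumours with those labels, with the class gene as a covariate, and the difference of that effect between BC74C and ZNF668 from the 13 of them with these class genes. The class genes' own transcripts were compared with exact permutation tests and the label table with 100000 permutations. Correlations used 100000 permutations with Benjamini-Hochberg adjustment over 7 relations.

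Before the data were examined, 21 gene lists were fixed: ependymal and motile cilia, radial glia and neural stem, oligodendrocyte progenitor, mature oligodendrocyte, astrocyte, mature neuron, neuronal progenitor, microglia and macrophage, T and NK cell, antigen presentation and interferon, endothelial, pericyte and fibroblast, choroid plexus, red blood cell, proliferation, hypoxia and glycolysis, mesenchymal glioma, NF-kappaB target, Rab3 and exocytosis, BAF chromatin remodelling, and p53 target. Of their 402 genes 359 were measured and 332 tested. Lists were tested with camera at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry, adjusted over the 21 lists. No list passed with an estimated correlation in any comparison, and in each of the first 4 comparisons fry called 0 lists, in its directional as in its mixed test. At an unadjusted p under 0.05 its directional test had 1 list for BC74C minus ZNF668 and 0 for the other 3 of them.

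The tests, the alternatives named in the closing section unless it says otherwise, and the rule for naming genes were fixed at the same point. The rule names, per comparison, the 10 genes with the largest and the 10 with the smallest log2 difference among those called, or the 5 with the smallest p in each direction where fewer than 5 passed. It also names, for each list called by camera, the 2 members with the highest and the 2 with the lowest moderated t, and Rab3a, Bcl7c and Zfp668. Names from predictions or clones are passed over.

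The fit was tested on simulated data with 200 of 13218 genes changed. It recovered 57% of genes changed by 1 on the log2 scale and 88% of those changed by 2 between RAB3A and ZNF668, 71% and 89% between BC74C and ZNF668, and 58% and 92% between RAB3A and BC74C. For HGG minus ependymoma it recovered 38% and 81%, and for the difference of that effect between class genes 1% and 33%. The simulated noise was drawn once, independently for each gene and tumour. Real genes varied together along a main axis that held 40.3% of the variance, so these percentages are not the power of the real comparisons. Tumours labelled TUMOR or UNKNOWN were left out of the comparisons of tumour labels, and probe sets with several symbols or none of the comparisons of genes. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.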

Results

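RNA was profiled in 24 tumours excised from the cortex of mice, with 1 single-colour array per tumour. Per the labels, the cells each tumour came from expressed 1 of 3 class genes: RAB3A in 6 tumours, BC74C in 9 and ZNF668 in 9. RAB3A encodes a small GTPase of synaptic vesicles, and ZNF668 encodes a zinc finger protein whose mouse orthologue is Zfp668. BC74C is not an approved gene symbol; Bcl7c, which encodes a subunit of BAF chromatin remodelling complexes, is examined here only as a candidate for it. The tumours also carry a second label: 11 are labelled ependymoma, 4 HGG (an abbreviation the labels do not spell out), 5 TUMOR without a type and 4 UNKNOWN. Among the RAB3A tumours 2 are labelled ependymoma and 0 HGG, among the BC74C tumours 6 and 2, and among the ZNF668 tumours 3 and 2. Replicate numbers here follow the order of deposit within each class gene. The median log2 value of an array lay between 4.98 and 5.19, and 13218 genes were tested. The number of arrays limits the precision: the median standard error of a log2 difference was 0.23 between RAB3A and ZNF668 tumours and 0.20 between BC74C and ZNF668 tumours. The labels do not say that the tumours come from separate animals, so every p-value here measures only the spread between these samples.

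Whether the class genes give tumours of different types can be asked of the labels alone. The share of tumours labelled ependymoma did not differ detectably between the class genes (chi-square 2.52, permutation p = 0.386, 24 tumours). Among the 15 tumours labelled ependymoma or HGG the chi-square was 1.19 (permutation p = 0.793).

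The class genes' own mouse transcripts were compared first, as a check of the labels. Rab3a averaged a log2 value of 9.30 ± 0.86 (SD, n = 6) in RAB3A tumours and 8.65 ± 1.27 (SD, n = 18) in the others, a difference of 0.65 (two-sided exact permutation test, p = 0.259). Bcl7c averaged 9.06 ± 0.44 (SD, n = 9) in BC74C tumours and 8.57 ± 0.58 (SD, n = 15) in the others, a difference of 0.49 (exact p = 0.0397, 0.119 after Benjamini-Hochberg adjustment over the 3 transcripts). Its second probe set had the opposite sign, -0.29 (exact permutation p = 0.335). Zfp668 averaged 4.99 ± 0.26 (SD, n = 9) in ZNF668 tumours and 4.91 ± 0.32 (SD, n = 15) in the others, a difference of 0.08 (exact permutation p = 0.521), and its second probe set gave -0.25 (exact p = 0.105). An introduced gene of human sequence, or without the 3' end the probes cover, need not be seen by these probe sets.

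Across all 24 tumours, whatever the class gene, the mature neuron list (transcripts of differentiated neurons) varied from a mean log2 value of 4.74 in ZNF668 replicate 7 to 10.46 in RAB3A replicate 1. It ran opposite to the proliferation list of cell cycle genes (Pearson's r = -0.73, permutation p = 4e-05, adjusted over 7 relations 9.33e-05; Spearman's rho = -0.74, permutation p = 8e-05, adjusted 0.00028). Without the 2 tumours farthest from the median of the proliferation list r was -0.69. It was -0.81 within the 18 tumours whose titles begin with elw and -0.51 within the 6 that begin with mmr. The neuron list averaged 9.23 ± 1.18 (SD, n = 6) in RAB3A, 8.61 ± 1.43 (SD, n = 9) in BC74C and 7.88 ± 1.61 (SD, n = 9) in ZNF668 tumours. The list also ran opposite to the mean of the Y-linked transcripts Eif2s3y, Kdm5d and Uty (r = -0.52, permutation p = 0.00948, adjusted 0.0111; rho = -0.62, permutation p = 0.00177, adjusted 0.00248) and along with Xist, the transcript of the inactive X chromosome (r = 0.74, permutation p = 3e-05, adjusted 9.33e-05; rho = 0.71, permutation p = 0.00012, adjusted 0.00028). Without the 2 farthest tumours these r were -0.49 and 0.83, within elw -0.66 and 0.56, and within mmr -0.76 and 0.93.

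**Figure D1:**
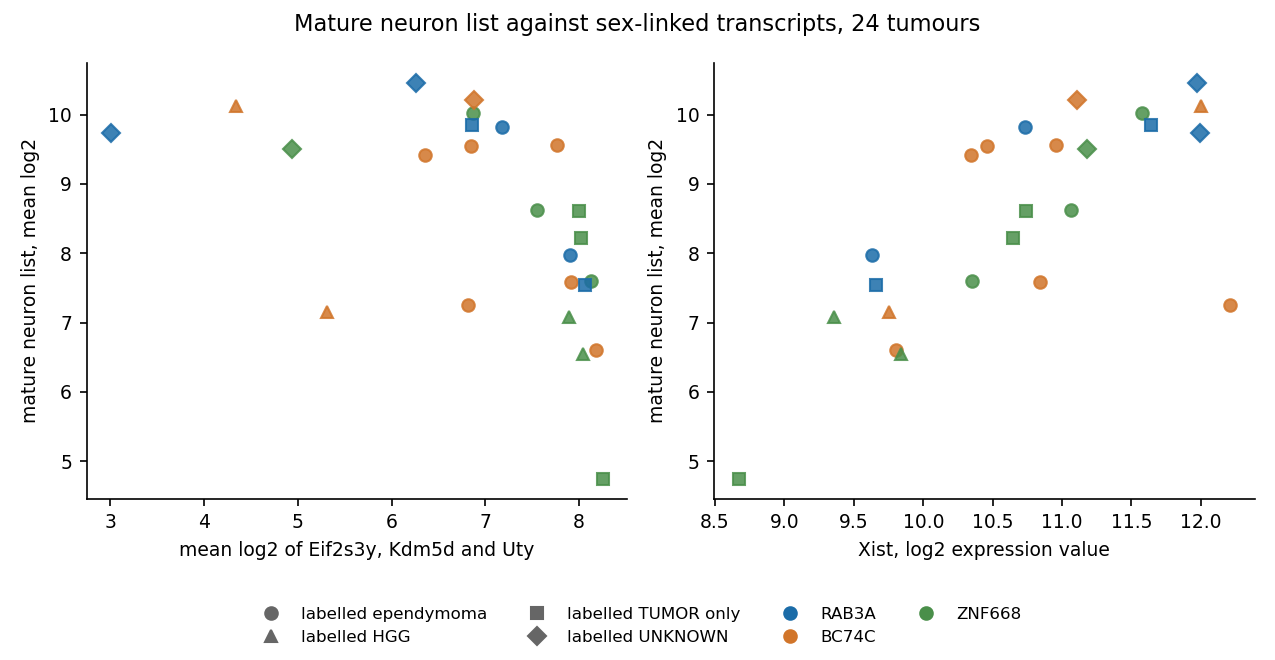
Mean log2 value of the mature neuron list against the mean of 3 Y-linked transcripts (left) and against Xist (right) in the 24 tumours; each point is a tumour, its colour gives the class gene and its shape the tumour label. The neuron list falls as the Y-linked mean rises (r = -0.52) and rises with Xist (r = 0.74), and RAB3A replicate 5 has the lowest Y-linked mean at 3.01.

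RAB3A tumours had less Gsta2, Smco3, Proca1 and Angptl6 transcript than ZNF668 tumours and far more Gdpd3. Gsta2, a glutathione S-transferase of detoxification, averaged 4.32 ± 1.73 (SD, n = 6) in RAB3A against 7.82 ± 1.32 (SD, n = 9) in ZNF668 tumours, a log2 difference of -3.50 (SE 0.60, limma adjusted p = 0.0381). It lay below the ZNF668 mean in 5 of 6 RAB3A tumours; RAB3A replicate 6, at 7.85, was the exception. Gdpd3, a glycerophosphodiester phosphodiesterase, rose by 4.05 (SE 0.76, limma adjusted p = 0.04), from 5.97 ± 1.78 (SD, n = 9) in ZNF668 to 10.01 ± 0.92 (SD, n = 6) in RAB3A tumours, with 6 of 6 RAB3A tumours above the ZNF668 mean. The other named genes that fell were Smco3 at -2.74, Proca1 at -2.69, Angptl6 (a secreted angiopoietin-like protein) at -2.18, Slc27a3 (a fatty acid transport protein) at -1.84, Nol3 (an inhibitor of apoptosis) at -1.71, the non-coding Abhd11os at -1.58 and Opn3 (an opsin) at -1.52, with adjusted p between 0.0381 and 0.0416. Smco3 was lower than the ZNF668 mean in 5 of 6 RAB3A tumours, where it was at most 3.37, also a dim value. The rest were lower in 6 of 6. Each of these 9 calls was lost in 12 to 19 of the 24 fits that left out 1 tumour.

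The mature neuron list was higher in RAB3A than in ZNF668 tumours: 21 of 21 measured members had a positive difference and their mean was 1.35 (camera adjusted p = 2.82e-08 with a preset correlation of 0.01; adjusted p = 0.833 with an estimated correlation). Neurod6 and Tbr1, transcription factors of cortical excitatory neurons, differed by 2.46 (SE 0.86) and 2.004 (SE 0.86). Slc32a1, the vesicular GABA transporter, differed by 0.60 and Nefm, a neurofilament subunit, by 0.49. The Rab3 and exocytosis list was also higher, with 9 of 12 members positive and a mean of 0.56 (camera adjusted p = 0.023, and 0.833 with an estimated correlation). Across all tumours this list and the neuron list both followed the main axis of variation (r = 0.96 and 0.93), so they are not separate results. Within the Rab3 list Stx1a differed by 0.92 and Rims1 by 1.48, both of the presynaptic release site, while Rph3al differed by -0.11 and Sytl4 by -0.34. Motile cilia genes had a small positive mean of 0.22 with 21 of 27 positive (camera adjusted p = 0.0156; adjusted p = 0.833 with an estimated correlation), which was 0.06 without RAB3A replicates 5 and 6 (adjusted p = 0.278). Dnah11, an axonemal dynein, differed by 0.33 and Enkur by 1.02, whereas the cilia regulators Foxj1 and Rfx3 differed by -0.37 and -0.33. The proliferation list was lower, 23 of 23 members negative with a mean of -0.73 (camera adjusted p = 0.0248; adjusted p = 0.833 with an estimated correlation). Birc5, a survivin that acts in mitosis, differed by -1.18, Aurka by -1.15, Mki67 by -0.65 and Rrm2 by -0.50. With the neuron and oligodendrocyte list means as covariates Mki67 and Rrm2 took the opposite sign, at 0.64 and 0.49. No member of the 21 lists passed over all genes tested by limma or adjusted over the list alone (0 and 0 of 332 members). The proliferation call was lost without any 1 of RAB3A replicates 1, 2, 4 and 6 and ZNF668 replicates 2, 6, 7 and 8, that of the Rab3 list without RAB3A replicate 4 or ZNF668 replicate 2 or 7, and that of cilia genes without RAB3A replicate 4 or 5. The proliferation mean was -0.40, -0.43 and -1.17 without RAB3A replicate 1, 2 and 5, -1.25 without both 5 and 6, and -0.48 without ZNF668 replicate 8, and the cilia mean 0.37, 0.10 and 0.07 without RAB3A replicate 3, 4 and 5. With the Y-linked mean as a covariate, an alternative chosen after the results were seen, the neuron mean was 0.87 and 3 calls were lost: proliferation at -0.55 (adjusted p = 0.113) and the Rab3 and cilia lists at 0.26 and 0.08 (adjusted p = 0.206 each). Other probe sets had the opposite sign for Slc32a1 (-0.0097), Rph3al (0.0057), Sytl4 (0.0052) and Zfp668 (0.48). Rab3a itself differed by 0.75 (SE 0.60, limma adjusted p = 0.632), Bcl7c by -0.54 and Zfp668 by -0.20.

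In all, limma called 10 genes at an adjusted p under 0.05, 1 higher and 9 lower, with 1217 at an unadjusted p under 0.05 where 661 are expected by chance. The only called gene left unnamed has a name from a clone or prediction. The count was 40 without RAB3A replicate 6, 28 without ZNF668 replicate 9, between 4 and 6 without ZNF668 replicate 1 or 7 or BC74C replicate 2, 5 or 9, and 0 (limma; 713 to 1921 at an unadjusted p under 0.05) without any 1 of RAB3A replicates 1 to 5, ZNF668 replicates 2, 3, 4, 6 and 8 and BC74C replicates 6 and 8. With the title prefix as a block it was 7, within elw 21, within mmr 0 (229 unadjusted), and with the neuron and oligodendrocyte list means as covariates 0 (475 unadjusted), where Gsta2 still differed by -2.89 and Gdpd3 by 3.18. Limma also called 0 with only these class genes compared, among tumours labelled ependymoma and with the Y-linked covariate, and 21 with array weights.

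**Figure D2:**
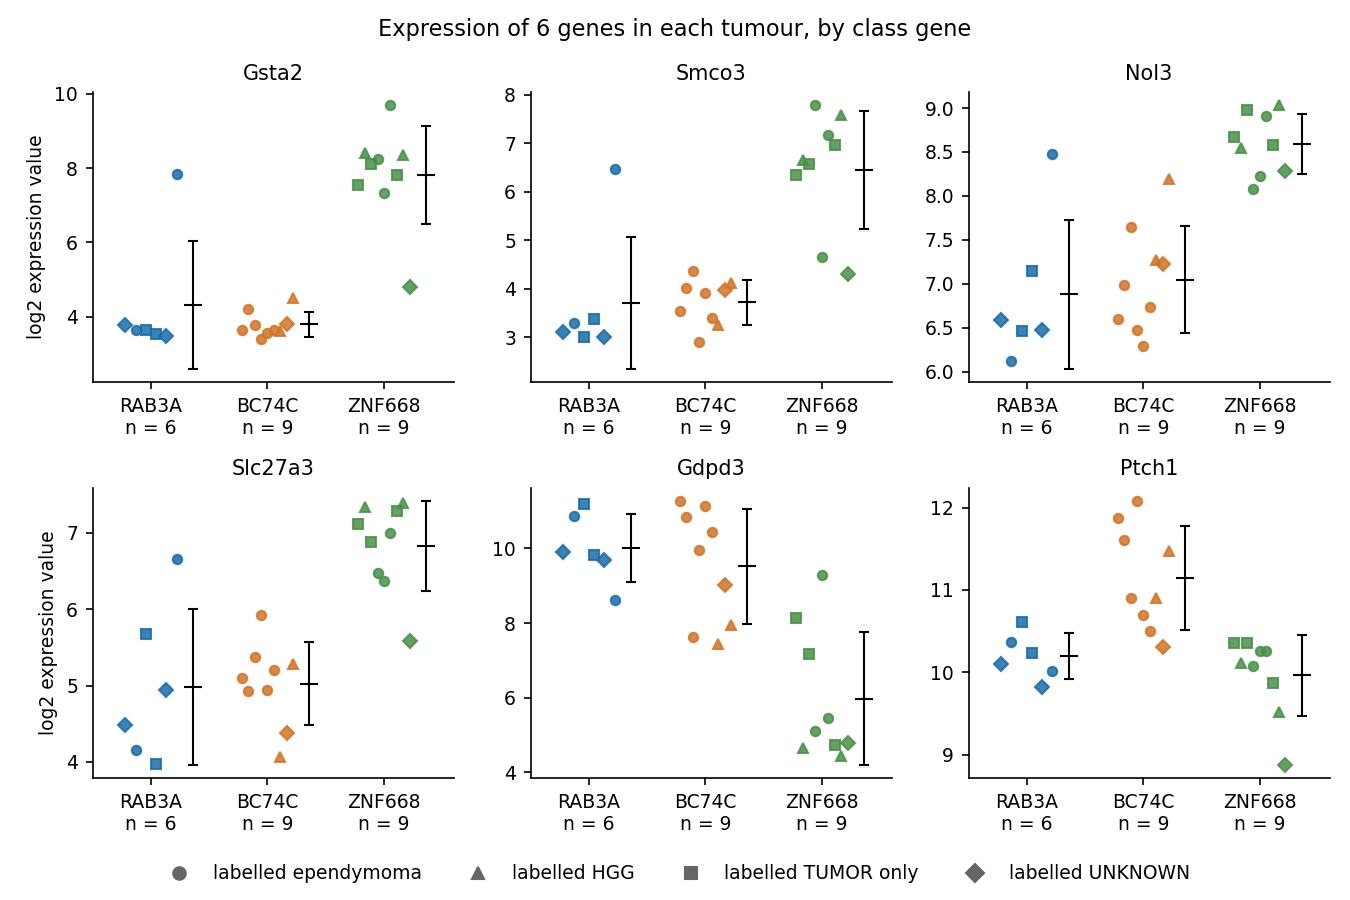
Log2 expression values of 6 genes in each of the 24 tumours, by class gene; each point is a tumour, its shape gives the tumour label, and the bar is the mean ± SD. Gsta2 averages 7.82 in ZNF668 tumours against 4.32 and 3.79 in RAB3A and BC74C tumours, with RAB3A replicate 6 at 7.85.

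BC74C tumours, like RAB3A tumours, had less Gsta2 and more Gdpd3 than ZNF668 tumours, and they also had more Ptch1. Gsta2 fell by 4.03 on the log2 scale (SE 0.53, limma adjusted p = 0.00123), to 3.79 ± 0.34 (SD, n = 9), and all 9 of 9 BC74C tumours lay below the ZNF668 mean. Gdpd3 rose by 3.55 (SE 0.68, limma adjusted p = 0.0171; 9 of 9 above). Ptch1, the receptor and target gene of Hedgehog signalling, rose by 1.18 (SE 0.23, limma adjusted p = 0.0171), from 9.96 ± 0.49 (SD, n = 9) to 11.15 ± 0.63 (SD, n = 9); its other probe set differed by 0.16. Gria1, an AMPA receptor subunit, rose by 1.95 (SE 0.42, limma adjusted p = 0.039), a call lost in 12 of the 24 fits that left out 1 tumour (adjusted p up to 0.0975).

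The other named genes that rose were Rhbdd1 (a rhomboid protease) by 1.71, Rnf182 (a ubiquitin ligase) by 1.67, Frem1 (an extracellular matrix protein) by 1.57, Serinc2 by 1.42, N4bp3 by 1.35, Gnpnat1 (of the hexosamine pathway) by 1.01 and Polrmt (the mitochondrial RNA polymerase) by 0.81. Those that fell were Proca1 at -2.79, Smco3 at -2.73, Edaradd (an adaptor of the ectodysplasin receptor) at -2.15, Aard at -2.14, Angptl6 at -1.97, Gpx3 (the secreted glutathione peroxidase) at -1.84, Tfap2e (a transcription factor) at -1.84, Slc27a3 at -1.80 and Fndc1 at -1.78. Their adjusted p lay between 0.00256 and 0.0497, and each differed in its direction from the ZNF668 mean in 9 of 9 BC74C tumours, or in 8 of 9 for Serinc2. Leaving out 1 tumour ended the call of Serinc2 in 20 of 24 fits, of Polrmt in 14, Aard in 13, N4bp3 in 7, Edaradd in 5 and Fndc1 in 4, and of the other genes named here, Gria1 apart, in 0. Of 3 other probe sets of Edaradd, 1 had the opposite sign, at 0.08.

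The oligodendrocyte progenitor list was lower in BC74C than in ZNF668 tumours, 11 of 11 members negative with a mean of -0.93 (camera adjusted p = 9.46e-07; adjusted p = 0.508 with an estimated correlation). Adjusted over the list alone 3 members passed, Lhfpl3 at -1.39, Tnr at -1.29 and Pcdh15 at -1.38, and 0 passed over all genes tested by limma; the lineage regulators Olig1 and Olig2 differed by only -0.32 and -0.59. Endothelial genes were lower as a list, with 15 of 17 negative and a mean of -0.36 (camera adjusted p = 0.000226; adjusted p = 0.983 with an estimated correlation), and without ZNF668 replicate 9 their mean was -0.17 (adjusted p = 0.183). Esam and Eng, of the endothelial surface, differed by -0.57 each, and Podxl and the efflux pump Abcb1a by 0.02 and 0.0042. Antigen presentation and interferon genes were higher, with 16 of 16 positive and a mean of 0.49 (camera adjusted p = 0.00253; adjusted p = 0.983 with an estimated correlation). H2-K1, a class I histocompatibility gene, differed by 0.46, Gbp3 by 0.61, and the chemokines Cxcl9 and Cxcl10 by 0.35 and 0.26. The mature neuron list was higher, with 20 of 21 positive and a mean of 0.72 (camera adjusted p = 0.00247; adjusted p = 0.983 with an estimated correlation). Neurod6 differed by 1.74 and Cck by 1.35, while the interneuron genes Slc32a1 and Sst differed by 0.03 and -0.11. The neuron call was lost with the title prefix as a block (mean 0.49, adjusted p = 0.0644) and without BC74C replicate 7 or 8 or ZNF668 replicate 7, and the antigen presentation call without ZNF668 replicate 5 or 9. The Y-linked covariate also ended the neuron call (mean 0.32, adjusted p = 0.386) and took the oligodendrocyte progenitor mean to -0.59. The neuron mean was 0.33 without ZNF668 replicate 7 and the antigen presentation mean 0.28 without ZNF668 replicate 9. Other probe sets had the opposite sign for Abcb1a (-0.14), Bcl7c (-0.32) and Zfp668 (0.09). Rab3a differed by 0.22, Bcl7c by 0.27 (SE 0.23) and Zfp668 by -0.0086.

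In all, limma called 40 genes, 11 higher and 29 lower, with 909 at an unadjusted p under 0.05. Of these, 9 were also called between RAB3A and ZNF668 tumours, 1 higher and 8 lower in both, where independent lists would share 0.0206. The comparisons share the ZNF668 tumours, which alone can make genes shared. With RAB3A compared with 1 part of them and BC74C with the rest, limma called 0 and 31 genes (375 and 1268 unadjusted) or 11 and 0 (2558 and 697 unadjusted), so sharing without common tumours could not be measured. The count was 63 without ZNF668 replicate 9 and 25 or 26 without ZNF668 replicate 1, 3 or 6 or BC74C replicate 8. It was 30 with the title prefix as a block, 46 within elw and 0 by limma among tumours labelled ependymoma (681 unadjusted). Within mmr BC74C is a single tumour, so no count is given.

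**Figure D3:**
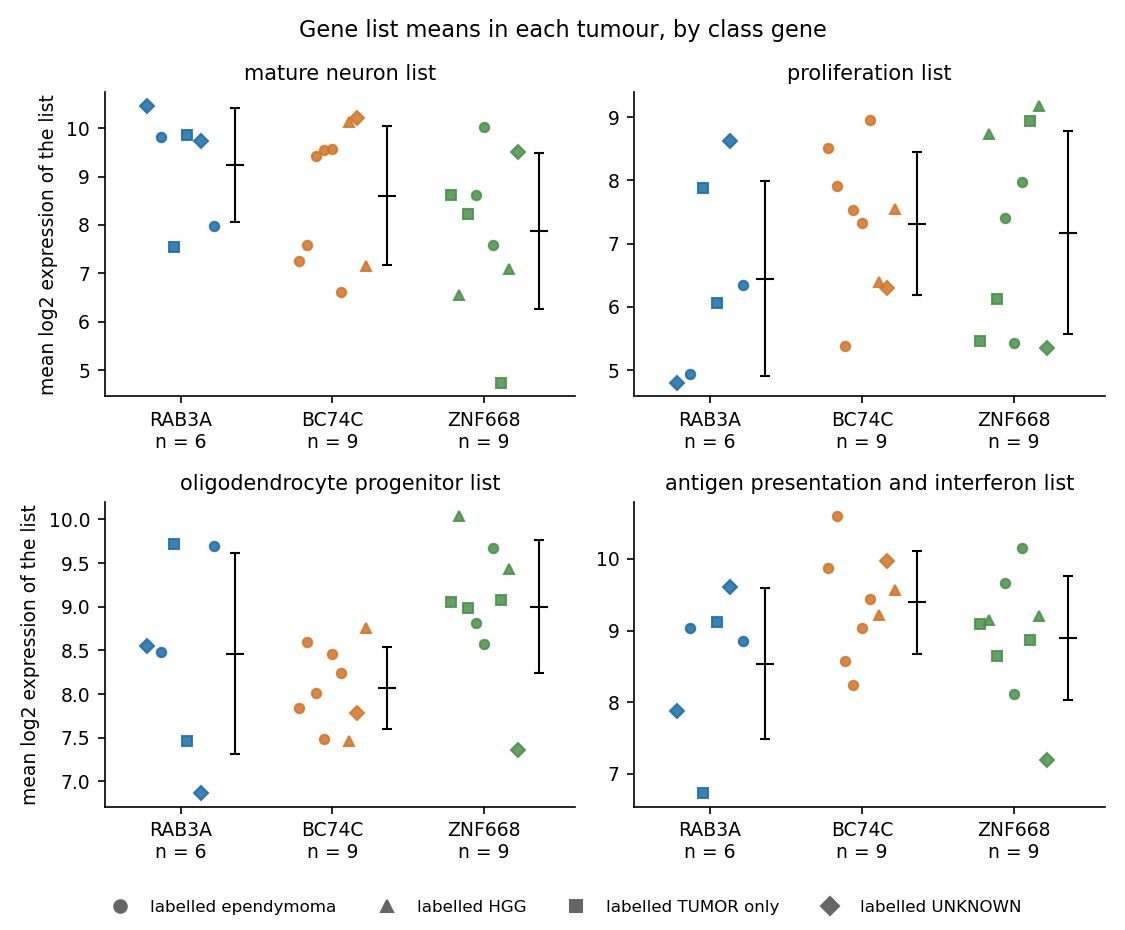
Mean log2 expression of 4 gene lists in each of the 24 tumours, by class gene; each point is a tumour, its shape gives the tumour label, and the bar is the mean ± SD. The oligodendrocyte progenitor list averages 8.07 in BC74C and 9.0003 in ZNF668 tumours, and the neuron list spreads from 4.74 to 10.46.

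Between RAB3A and BC74C tumours limma called 0 genes, with 1085 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0697. The genes with the smallest p, none of which passed, were lower in RAB3A tumours for Upp1 (uridine phosphorylase) by a log2 difference of -2.12 (SE 0.40), Adgrg6 (an adhesion receptor) at -2.43, Rdh5 (a retinol dehydrogenase) at -1.94, Rerg (a Ras-like GTPase) at -1.88 and Acy1 (an aminoacylase) at -0.88. Higher in RAB3A tumours were Igsf9b at 1.38, Taf9b (a subunit of the basal transcription machinery) at 1.18, Ralgps2 at 0.79, Mtmr1 at 0.68 and Usp34 (a deubiquitinase) at 0.50; 1 name from a clone or prediction was passed over. Upp1 averaged 6.13 ± 0.68 (SD, n = 6) in RAB3A and 8.25 ± 0.83 (SD, n = 9) in BC74C tumours.

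Antigen presentation and interferon genes were lower as a list in RAB3A than in BC74C tumours, with 14 of 16 negative and a mean of -0.85 (camera adjusted p = 4.27e-05; adjusted p = 0.923 with an estimated correlation). Adjusted over the list alone 4 members passed, Gbp3 at -1.29, Gbp2 at -1.58, H2-D1 at -0.76 and H2-K1 at -0.88, against 0 by limma over all genes; the class II genes Cd74 and H2-Aa differed by 0.21 and 0.05. The proliferation list was lower, with 23 of 23 negative and a mean of -0.87 (camera adjusted p = 0.00342; adjusted p = 0.923 with an estimated correlation). The replication genes Mcm2 and Mcm3 differed by -1.19 and -1.20, Mcm6 by -0.40 and Cenpe by -0.58. Radial glia and neural stem genes were lower, with 18 of 23 negative and a mean of -0.46 (camera adjusted p = 0.0101; adjusted p = 0.923 with an estimated correlation). Tnc, a matrix glycoprotein, differed by -2.42 (SE 0.89) and the filament gene Vim by -0.79, but Hopx and Prom1 by 0.43 and 0.31. The neuron list was higher, with 20 of 21 positive and a mean of 0.62 (camera adjusted p = 0.00359; adjusted p = 0.923 with an estimated correlation). Tbr1 differed by 0.97, the glutamate transporter Slc17a7 by 0.80, Gad2 by 0.30 and Nefm by -0.0012. Endothelial genes were higher, with 15 of 17 positive and a mean of 0.28 (camera adjusted p = 0.00947; adjusted p = 0.923 with an estimated correlation). The junction gene Cldn5 differed by 0.71 and Esam by 0.48, Kdr by -0.03 and Podxl by -0.05. The neuron call was lost without RAB3A replicate 1, that of proliferation without RAB3A replicate 1 or 2, and that of radial glia without RAB3A replicate 5 or BC74C replicate 4 or 5. Without RAB3A replicate 3, whose antigen presentation mean was the lowest of the RAB3A tumours at 6.73, that list differed by -0.49 (adjusted p = 0.0195). The proliferation mean was -0.54, -0.57 and -1.31 without RAB3A replicate 1, 2 and 5 and -1.39 without both 5 and 6, and the neuron mean 0.38 and 0.96 without RAB3A replicate 1 and 3 and 0.37 without BC74C replicate 6. Of the other probe sets, 1 had the opposite sign for each of Usp34 (-0.0037), H2-Aa (-0.23), H2-D1 (0.11), Bcl7c (0.26) and Zfp668 (0.38). Rab3a differed by 0.54, Bcl7c by -0.82 (SE 0.25, limma adjusted p = 0.353) and Zfp668 by -0.19. With the title prefix as a block limma called 2 genes, and the radial glia and endothelial lists had adjusted p = 0.0588 each. Limma called 4 genes without BC74C replicate 7 or without ZNF668 replicate 9, 3 without RAB3A replicate 6 and 2 without BC74C replicate 4.

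Between the tumours labelled HGG and ependymoma, compared with the class gene held constant (4 against 11), no single gene passed. Of the RAB3A tumours 2 are labelled ependymoma and 0 HGG, so those 2 enter only the estimate of the spread. The differences come from the BC74C tumours (2 HGG, 6 ependymoma) and the ZNF668 tumours (2 HGG, 3 ependymoma). Limma called 0 genes, with a smallest adjusted p of 0.9998. At an unadjusted p under 0.05 it had 229, where 661 are expected by chance. The genes with the smallest p, none of which passed, were lower in tumours labelled HGG for Gulp1 at -1.34 (SE 0.37), Plagl1 (a zinc finger transcription factor) at -1.10, Gli2 (a transcription factor of Hedgehog signalling) at -0.73, Sparc (a matrix protein) at -0.54 and Pls3 (an actin-bundling protein) at -0.42. Higher were Fam89a at 1.27, Car6 (a carbonic anhydrase) at 1.07, Myzap at 0.72, Rep15 at 0.69 and Slmap at 0.60; 2 names from clones or predictions were passed over. Gli2 averaged 7.41 ± 0.40 (SD, n = 4) in tumours labelled HGG and 8.19 ± 0.29 (SD, n = 11) in those labelled ependymoma, the 2 RAB3A tumours included.

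The proliferation list was higher in tumours labelled HGG, with 22 of 23 positive and a mean of 0.55 (camera adjusted p = 0.00121; adjusted p = 0.997 with an estimated correlation). Tk1 differed by 0.80, Rrm2 by 0.77, the checkpoint gene Bub1b by 0.29 and Foxm1 by -0.01. Astrocyte genes were lower, with 14 of 16 negative and a mean of -0.38 (camera adjusted p = 0.000751; adjusted p = 0.997 with an estimated correlation). The glutamate transporter Slc1a2 and the bicarbonate transporter Slc4a4 differed by -0.72 each, while S100b and Ntsr2 differed by 0.31 and 0.11. The neuron list was lower, with 20 of 21 negative and a mean of -0.69 (camera adjusted p = 0.00121; adjusted p = 0.997 with an estimated correlation). Sst differed by -1.53, Nefm by -1.24, Tbr1 by -0.22 and Neurod6 by 0.08. Rab3 and exocytosis genes were lower, with 10 of 12 negative and a mean of -0.39 (camera adjusted p = 0.0405; adjusted p = 0.997 with an estimated correlation). Rab3b differed by -0.93, Sytl4 by -0.43, Rims2 by 0.19 and Rab3il1 by 0.10. Rab3a differed by -0.63, Bcl7c by -0.11 and Zfp668 by -0.32. With the title prefix as a block none of these 4 lists passed. The means were 0.04 for proliferation (camera adjusted p = 0.921), -0.19 for astrocyte (0.172), 0.03 for neuron (0.921) and -0.10 for Rab3 and exocytosis genes (0.921). Of the 2 tumours labelled HGG under either class gene, 1 has an mmr title. The only tumour labelled ependymoma with such a title is RAB3A replicate 6. Prefix and label are thus partly confounded, and the block cannot tell their effects apart. Leaving out 1 tumour also ended calls: that of the neuron list without ZNF668 replicate 2 or 5 or BC74C replicate 9, of proliferation without ZNF668 replicate 2, 5 or 8 or BC74C replicate 3, of astrocyte genes without ZNF668 replicate 8, and of Rab3 and exocytosis genes without ZNF668 replicate 2, 4, 5 or 8 or BC74C replicate 3, 5 or 9. Without BC74C replicate 7, by contrast, the means grew to -1.62 for neuron (adjusted p = 2.64e-09), 1.16 for proliferation (5.21e-06) and -0.86 for Rab3 and exocytosis genes (0.0003). With the Y-linked covariate they also grew, to -1.93 for neuron, 1.82 for proliferation, -1.10 for Rab3 and exocytosis and -0.58 for astrocyte genes. The BC74C tumours labelled HGG had the lowest Y-linked means of the tumours compared (4.34 and 5.31). The covariate is thus partly tied to the label, and no conclusion is drawn from this growth. Without ZNF668 replicate 2 and 5 the means were -0.35 and -0.33 for neuron, 0.33 and 0.13 for proliferation and -0.23 and -0.20 for Rab3 and exocytosis genes. Without ZNF668 replicate 8 they were 0.18 for proliferation, -0.25 for Rab3 and exocytosis and -0.14 for astrocyte genes. Without BC74C replicate 9 the neuron mean was -0.38, and without BC74C replicate 3 the proliferation mean was 0.34. Other probe sets had the opposite sign for Bub1b (-0.16, 1 of 2), Rims2 (-0.18, 1 of 3), Foxm1 (0.02 to 0.23, 3 of 3), Bcl7c (0.05) and Zfp668 (0.02).

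The difference between tumours labelled HGG and ependymoma was itself compared between BC74C and ZNF668 tumours, with 2 tumours labelled HGG under each class gene. Pericyte and fibroblast genes were the most negative cell type list: 12 of 13 members had a lower HGG minus ependymoma difference in BC74C than in ZNF668 tumours, with a mean of -2.11 (camera adjusted p = 2.37e-06; adjusted p = 0.385 with an estimated correlation). The fibrillar collagen gene Col3a1 differed by -5.37 (SE 1.20), Kcnj8 by -2.98, Col6a1 by -0.84 and Vtn by 0.19. Endothelial genes had a mean of -0.66 with 12 of 17 negative (camera adjusted p = 0.00428; adjusted p = 0.532 with an estimated correlation). Pecam1 differed by -2.26 and Cdh5 by -1.71 (its other probe set by 0.10), both endothelial adhesion genes, against 1.75 for Slco1a4 and 1.60 for Ly6c1. The proliferation list had a mean of -2.65 with 23 of 23 negative (camera adjusted p = 8.79e-10; adjusted p = 0.532 with an estimated correlation), with Mcm3 at -3.08, Top2a at -2.90, Bub1b at -2.89 and Pcna at -0.79.

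The neuron list went the other way, with 20 of 21 positive and a mean of 2.24 (camera adjusted p = 1.09e-05; adjusted p = 0.532 with an estimated correlation). Grin2b, an NMDA receptor subunit, differed by 2.91 (its 2 other probe sets by -0.33 and -0.08), Gad1 by 2.49, Slc17a7 by 0.71 and Neurod6 by -0.84. Rab3 and exocytosis genes had a mean of 1.34 with 10 of 12 positive (camera adjusted p = 0.00515; adjusted p = 0.532 with an estimated correlation), with Rab3c at 3.99, Rph3a at 2.70, Rab3il1 at -0.05 and Sytl4 at -0.06. Microglia and macrophage genes had a mean of 0.58 and a median of 0.91 with 15 of 19 positive (camera adjusted p = 0.00287; adjusted p = 0.532 with an estimated correlation); Tmem119 of resident microglia differed by 2.24 and Ctss by 1.04, but Mrc1 and Lyz2 by -2.21 and -1.14. Motile cilia genes had a mean of 0.55 with 22 of 27 positive (camera adjusted p = 0.00343; adjusted p = 0.532 with an estimated correlation). Ccdc39 differed by 1.74, Tekt2 by 1.55, Iqcg by -0.46 and Mlf1 by -1.69. Radial glia and neural stem genes had a mean of -0.67 with 18 of 23 negative (camera adjusted p = 0.0382; adjusted p = 0.532 with an estimated correlation). The Notch target Hes5 differed by -3.02, Id1 by -2.07, Id4 by 0.57 and Prom1 by 0.43.

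With the Y-linked covariate 4 of these lists took the opposite sign: neuron at -1.83 (adjusted p = 0.0185), proliferation at 1.14 (0.0274), radial glia at 0.39 (0.0376) and Rab3 and exocytosis genes at -1.07 (0.0502). Pericyte and fibroblast genes kept theirs, at -2.24, as did cilia genes at 0.33 (camera adjusted p = 0.323), microglia at 1.64 and endothelial genes at -1.53. The 2 BC74C tumours labelled HGG had Y-linked means of 4.34 and 5.31, against 6.36 to 8.18 in the other tumours compared. The covariate is therefore hardly separable from the difference tested, and no conclusion is drawn from these sign changes.

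No single gene passed in this comparison: limma called 0 genes, with 1079 at an unadjusted p under 0.05 and a smallest adjusted p of 0.591. The genes with the smallest p, none of which passed, were Lhx8 (a homeobox gene) at 4.22, Synpo2 at 3.60, Ifit1bl1 at 2.20, Cnih2 (an AMPA receptor auxiliary protein) at 1.94 and Dop1b at 1.92, and in the other direction Tfpi (an inhibitor of coagulation) at -3.41, Tdg (a DNA glycosylase) at -2.62, Troap at -2.17, Dut at -1.81 and Srsf2 (a splicing factor) at -1.01. Rab3a differed by 1.60, Bcl7c by -0.90 and Zfp668 by -0.15. Adjusted over the list alone 13 list members passed, 6 of them pericyte and fibroblast and 5 endothelial, against 0 by limma over all genes. A test for change in either direction, fry's mixed test, called 2 lists, endothelial and pericyte and fibroblast (adjusted p = 0.0259 each), and its directional test called 0. Without BC74C replicate 7 the neuron list mean was 0.75 (adjusted p = 0.152), that of Rab3 and exocytosis genes 0.66 (adjusted p = 0.17) and that of radial glia -0.47 (adjusted p = 0.303), and limma called 2 genes; without BC74C replicate 9 the endothelial mean was -0.26 (adjusted p = 0.438). The radial glia call was also lost without BC74C replicate 4, 5 or 6 or ZNF668 replicate 2 or 5, and limma called 1 gene without ZNF668 replicate 2 or 6. The endothelial mean was -1.05 without BC74C replicate 7, the neuron and Rab3 means 3.73 and 2.02 without BC74C replicate 9, the microglia mean 0.28 without ZNF668 replicate 6 and the radial glia mean -0.43 without ZNF668 replicate 2. Of the other probe sets, 1 also had the opposite sign for each of Ccdc39 (-0.10), Id4 (-0.23), Sytl4 (0.22) and Zfp668 (0.53).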

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

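The tests of host brain tissue, of RNA degradation and of loss of the Y chromosome, and all relations and uses of the Y-linked mean, were chosen after the values were seen.

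In groups of 4 to 9 tumours, the gap between the farthest tumour and its nearest neighbour was set against the group's range by Dixon's test, which picks out about 1 in 20 groups by chance. Of 274 groups 24 had such a tumour, where 13.7 are expected. ZNF668 replicate 9 supplied 5 of them, RAB3A replicate 6 supplied 4, and BC74C replicates 4 and 7 supplied 3 each. In RAB3A replicate 6 Gsta2 was 7.85 (next RAB3A tumour 3.78), Smco3 6.48 (3.37), Angptl6 8.20 (6.95) and Abhd11os 6.304 (5.02). In ZNF668 replicate 9 Gsta2 was 4.79, the progenitor gene Olig1 11.53, Esam 8.82, Podxl 9.19 and the endothelial list mean 8.57. In BC74C replicate 4 Acy1 was 6.73, Gnpnat1 6.79 and Zfp668 5.76. Among the tumours labelled HGG, BC74C replicate 7 stood apart with a neuron list mean of 10.13, Ly6c1 of 10.54 and Car6 of 3.21, BC74C replicate 9 with Slc4a4 of 10.93 and ZNF668 replicate 8 with an astrocyte list mean of 9.37. ZNF668 replicate 5 had Tbr1 of 7.01 and Stx1a of 7.45, ZNF668 replicate 1 Gpx3 of 7.79 and ZNF668 replicate 6 Zfp668 of 5.55. BC74C replicate 3 had Polrmt of 9.003, BC74C replicate 2 Rhbdd1 of 8.56 and RAB3A replicate 3 Nefm of 7.53.

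RAB3A replicate 6 had values like those of ZNF668 tumours: of 46 genes called between BC74C and ZNF668 tumours without it, 38 (82.6%) lay on the ZNF668 side, against 8.70% to 26.1% in the other RAB3A tumours. A wrong class gene label may account for this: of 19 genes that separate the other RAB3A tumours from ZNF668 tumours but not BC74C from ZNF668 tumours, chosen without this tumour, 18 (94.7%) lay on the ZNF668 side. An exchange of labels needs a partner. The ZNF668 tumour most on the RAB3A side was replicate 9 with 92 of 120 genes (76.7%). This lay between the bounds of 50 and 80 set beforehand, so an exchange and a single wrong label cannot be told apart. ZNF668 replicate 9 also stood apart in other ways. It had the highest 3' minus 5' difference of the Actb control probe sets (1.11) and the highest mature oligodendrocyte list mean (10.54). Its astrocyte and radial glia list means, 7.92 and 7.18, were the lowest of all tumours. Whether RNA degradation or normal brain put this tumour on the RAB3A side was not tested. For RAB3A replicate 6 the amount of normal brain also stays open. With the neuron and oligodendrocyte list means removed, 67.4% of genes lay on the ZNF668 side in it, between the same bounds. The tumour is labelled ependymoma, and no biological explanation was tested.

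The mature neuron list varied between tumours along the main axis, which held 40.3% of the variance of all genes. A candidate explanation is brain tissue of a female host carried in with male tumour cells: the neuron list ran opposite to the Y-linked mean (r = -0.52), as such tissue would make it. Such tissue would also bring Xist and oligodendrocytes, and r was -0.57 between the Y-linked mean and Xist (-0.27 within BC74C tumours) and 0.62 between the oligodendrocyte and neuron lists, but -0.15 within the 6 RAB3A tumours. RNA degradation is not excluded, since the neuron list also rose with the 3' minus 5' difference of the Actb control probe sets (r = 0.45, permutation p = 0.0268, adjusted 0.0268; rho = 0.50, permutation p = 0.0136, adjusted 0.0159; 0.40 without the 2 farthest tumours, 0.57 within elw, 0.47 within mmr). With that difference held constant the r of Y-linked mean and neuron list was -0.38, between the bounds of -0.2 and -0.5, and a difference of the tumour cells themselves was not tested.

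RAB3A replicate 5 had a Y-linked mean of 3.01, where the next lowest tumour, BC74C replicate 7, had 4.34, and an Xist value of 11.99. Its proliferation list mean of 8.63 ranks 20 of 24 from the lowest, which argues against host tissue without dividing cells. Dividing host cells would also raise this list, so it cannot exclude host tissue without tumour cells. Of the 24 tumours it had the highest T and NK cell list mean (5.48) and the lowest oligodendrocyte progenitor mean (6.87). Loss of the Y chromosome from male tumour cells could also leave no Y-linked transcript; Xist lay 1.24 residual SD above the value given by the neuron list in the other tumours, between the bounds of 1 and 2, so loss of Y and a tumour of female cells cannot be told apart. The sex of hosts and of the introduced cells is not in the labels.

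The tumours were divided at random into groups of the same sizes, with 100 splits per comparison, the real one included. As many genes as the real 10 between RAB3A and ZNF668 tumours came from 3 splits, the real one included, with no adjustment over comparisons. A random split called 480, and leaving out 1 tumour could take the real count to 0, so chance was not excluded. As many as the real 40 between BC74C and ZNF668 tumours came from 1 split, the real one, and the highest other split called 0 by limma. Chance can be excluded there only if the tumours are independent samples, which the labels do not say. For RAB3A against BC74C and for HGG against ependymoma the real count was 0 by limma (1085 and 229 at an unadjusted p under 0.05). Any split gives at least 0, so that all 100 gave as many was fixed in advance and says nothing about chance. The highest other splits called 447 and 3940 genes. Splits that call so many genes point to a structure of the samples, and which structure stays open. The neuron list differed by -1.74, 1.91 and 1.98 between the groups of the 480-gene, 447-gene and 3940-gene splits. For the 447-gene and 3940-gene splits this was the largest such difference among the random splits of the comparison. For RAB3A against ZNF668 the largest was -1.77. Only 3, 7 and 5 of the other splits of those comparisons called any gene, too few to relate the calls to the neuron list. Between BC74C and ZNF668 a split with a neuron list difference of -1.91 called 0 genes by limma. In share of elw titles the groups of those 3 highest splits differed by -27.8, 33.3 and 27.3 percentage points. With the title prefix as a block the real counts were 7, 2 and 0 by limma (1258, 1184 and 135 at an unadjusted p under 0.05).

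The HGG minus ependymoma difference differed between BC74C and ZNF668 tumours for 8 lists by camera with the preset correlation (adjusted p between 0.385 and 0.532 with an estimated correlation): motile cilia by 0.55, radial glia by -0.67, neuron by 2.24, microglia by 0.58, endothelial by -0.66, pericyte and fibroblast by -2.11, proliferation by -2.65 and Rab3 and exocytosis by 1.34. With the Y-linked mean as a covariate the radial glia, neuron, proliferation and Rab3 differences took the opposite sign, at 0.39, -1.83, 1.14 and -1.07. That covariate is hardly separable from the difference tested. The BC74C tumours labelled HGG, with 4.34 and 5.31, had the lowest Y-linked means of the tumours compared.

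Probe sets without a gene symbol stand outside the comparisons of genes. Of 9797 of them tested, limma called 2 between RAB3A and ZNF668 tumours, 11 between BC74C and ZNF668 tumours and 0 between RAB3A and BC74C tumours. The same 2 probe sets led both comparisons with ZNF668: 1 differed by -2.83 in RAB3A and -3.20 in BC74C tumours, and the other by -1.54 and -1.77.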

How the results depend on the processing

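The alternatives without RAB3A replicates 5 and 6, those with the Y-linked mean as a covariate and, for the difference of the HGG effect between class genes, those with the title prefix or the list covariates were chosen after the results were seen, and the cause of the shifts given here was not tested.

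The 10 genes called between RAB3A and ZNF668 tumours depended on the model. Limma called 6 with no filter on dim probe sets, 21 with array weights (all 10 among them), 21 within elw (8 of the 10) and 21 without RAB3A replicates 5 and 6 (all 10). It called 0 within mmr (229 at an unadjusted p under 0.05), with the neuron and oligodendrocyte list means as covariates (475), among tumours labelled ependymoma (400), with only the 2 class genes compared (1159) and with the Y-linked covariate (685). The other 10 alternatives gave 7 to 12. Leaving out 1 tumour gave 0 to 40.

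The 40 genes called between BC74C and ZNF668 tumours became 23 with the dim filter at the median and 130 with array weights (all 40 among them). Limma called 0 among tumours labelled ependymoma (681 unadjusted). The fit within mmr, where BC74C is a single tumour, is given no count. The other 15 alternatives gave 30 to 50, and leaving out 1 tumour gave 25 to 63.

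For RAB3A minus BC74C, where limma called 0 (1085 unadjusted), it called 1 with no dim filter and with the Y-linked covariate. It called 2 with the dim filter at the median, no intensity trend, centred arrays, the prefix block, the list covariates or RAB3A replicates 5 and 6 left out. Leaving out 1 tumour gave 0 to 4. For HGG minus ependymoma it called 0 in each alternative (135 to 2245 unadjusted), and the comparison could not be fitted within mmr. For the difference of that effect between class genes it called 0 in each of the 14 alternatives fitted (906 to 2342 unadjusted), and leaving out 1 tumour gave 0 to 2. Within mmr this too could not be fitted. The prefix block leaves these differences as they are, since 1 of the 2 tumours labelled HGG is mmr under either class gene. No paired analysis was possible, because the labels give no replicate numbers.

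Each called gene named was followed through 18 or 19 alternatives. For RAB3A minus ZNF668 the calls held in 109 results, were lost in 60 and changed sign in 1. For BC74C minus ZNF668 they held in 293 and were lost in 82, the fit within mmr with its single BC74C tumour included. List calls, over all 5 comparisons together, held in 83, were lost in 38 and changed sign in 5. Adjusted p of the neuron list ranged from 0.00203 to 0.983 over the alternatives for BC74C minus ZNF668, and from 4.74e-10 to 0.997 for HGG minus ependymoma. That of the radial glia list ranged from 0.00375 to 0.923 and that of the endothelial list from 0.00985 to 0.923 for RAB3A minus BC74C. The proliferation, astrocyte and Rab3 lists ranged from 5.15e-16, 0.000941 and 2.12e-05 to 0.997 for HGG minus ependymoma.

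Leaving out 1 tumour moved many list means by over 1.5 times, as given with the results. The prefix block moved all 4 lists called for HGG minus ependymoma as far. Among the remaining alternatives, list means that moved by over 1.5 times did so mainly with the Y-linked covariate. For RAB3A minus ZNF668 it took the cilia mean to 0.08 and the Rab3 mean to 0.26 (adjusted p = 0.206 for both), and the neuron mean to 0.87 (adjusted p = 3.38e-05). The proliferation mean, at -0.55, also no longer passed (adjusted p = 0.113). Without RAB3A replicates 5 and 6 the cilia mean was 0.06 (adjusted p = 0.278) and the proliferation mean -1.25 (adjusted p = 0.000123). For BC74C minus ZNF668 the Y-linked covariate took the oligodendrocyte progenitor mean to -0.59 (adjusted p = 0.000239) and the neuron mean to 0.32 (adjusted p = 0.386). For RAB3A minus BC74C the proliferation mean was -1.39 without RAB3A replicates 5 and 6, and the radial glia list did not pass with the ependymoma label as a covariate (-0.36, adjusted p = 0.054). For HGG minus ependymoma the Y-linked covariate gave -1.93 for neuron, 1.82 for proliferation, -1.10 for Rab3 and -0.58 for astrocyte genes. There it is partly tied to the label, so no conclusion is drawn from these values. For the difference of the HGG effect between class genes the Y-linked covariate changed the sign of 4 lists. They became -1.83 for neuron (camera adjusted p = 0.0185), 1.14 for proliferation (0.0274), 0.39 for radial glia (0.0376) and -1.07 for Rab3 and exocytosis genes (0.0502). The covariate gave 0.33 for cilia (0.323), 1.64 for microglia and -1.53 for endothelial genes. In this comparison the covariate is hardly separable from the difference tested, since the BC74C tumours labelled HGG had the lowest Y-linked means (4.34 and 5.31).

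Of the other results that had passed as reported, 2 changed sign: Proca1, to 0.048 within mmr for RAB3A minus ZNF668, and the neuron list, to 0.0275 with the prefix block for HGG minus ependymoma. The rest that changed sign are named list members and class genes' transcripts, given here with the log2 difference each took. For RAB3A minus ZNF668, with array weights, Rph3al was 0.11. Within elw Slc32a1 was -0.26 and Nefm -0.24. Within mmr Proca1 was 0.048, Foxj1 0.19 and Mki67 0.11. With the list covariates Slc32a1 was -0.32, Nefm -0.41, Rrm2 0.49, Mki67 0.64 and Rab3a -0.18. Among tumours labelled ependymoma Foxj1 was 0.87, Slc32a1 -0.32, Nefm -0.73 and Rab3a -0.19. For BC74C minus ZNF668, after quantile normalization, Abcb1a was -0.0063 and Zfp668 0.014. With centred arrays Zfp668 was 0.015. With array weights Cxcl10 was -0.028. With the prefix block Slc32a1 was -0.21. Within elw Slc32a1 was -0.45, Cxcl10 -0.33 and Zfp668 0.012. Within mmr, where BC74C is a single tumour, Olig1 was 0.69, Olig2 1.20, Neurod6 -1.09, Slc32a1 -0.092, Cxcl9 -0.38, Podxl -0.81, Abcb1a -0.91 and Rab3a -0.85. With the list covariates Slc32a1 was -0.43, Abcb1a -0.081 and Rab3a -0.27. With the ependymoma label as a covariate Slc32a1 was -0.086. Among tumours labelled ependymoma Slc32a1 was -1.38, Cxcl9 -0.045, Cxcl10 -0.53, Esam 0.10, Rab3a -0.60 and Zfp668 0.017. With the Y-linked covariate Slc32a1 was -0.41, Podxl -0.13, Abcb1a -0.21, Rab3a -0.13 and Zfp668 0.020. For RAB3A minus BC74C, after quantile normalization, Nefm was 0.019. With array weights Nefm was 0.017, Cd74 -0.050, H2-Aa -0.15 and Podxl 0.068. With the prefix block Nefm was 0.22 and H2-Aa -0.14. Within elw Gad2 was -0.37, Cd74 -1.03, H2-Aa -1.04 and Kdr 0.0006. Within mmr, again with a single BC74C tumour, Tnc was 0.010, Nefm 1.84, Kdr 0.56, Mcm6 0.69 and Cenpe 0.12. With the list covariates Gad2 was -0.067 and Kdr 0.052. With the ependymoma label as a covariate Nefm was 0.20. Among tumours labelled ependymoma Nefm was 0.22. Without RAB3A replicates 5 and 6 Gad2 was -0.20, Cd74 -0.78, H2-Aa -0.87 and Kdr 0.11. For HGG minus ependymoma, with array weights, Neurod6 was -0.28, Foxm1 0.27, Rims2 -0.084 and Bcl7c 0.032. With the prefix block Tbr1 was 0.83, Bub1b -0.11, Foxm1 0.0099, Rab3il1 -0.20 and Rab3a 0.085. Within elw Tbr1 was 0.49, Foxm1 0.047, Rab3il1 -0.16 and Rab3a 0.13. With the list covariates Tbr1 was 0.70, Bub1b -0.11 and Rab3il1 -0.073. Without the class gene covariate Neurod6 was -0.20 and Foxm1 0.15. With the Y-linked covariate Ntsr2 was -0.29, Neurod6 -0.25, Foxm1 0.45, Rims2 -0.45 and Bcl7c 0.29. For the difference of the HGG effect between class genes, with array weights, Sytl4 was 0.032. Within elw Neurod6 was 2.51 and Sytl4 0.20. With the list covariates Prom1 was -0.16, Id4 -0.38, Slc17a7 -1.45, Lyz2 0.0062, Vtn -0.32, Rab3il1 0.39, Sytl4 0.025 and Rab3a -0.26. With the Y-linked covariate Iqcg was 0.72, Id4 -1.51, Gad1 -0.11, Slc17a7 -2.41, Lyz2 1.29, Ly6c1 -0.19, Vtn -1.51, Pcna 0.94, Top2a 2.48, Mcm3 0.012, Bub1b 0.44, Rab3c -0.33, Rph3a -1.52, Rab3il1 0.65 and Rab3a -2.56.

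Leaving out 1 tumour at a time changed the sign of 32 results, given with the tumour left out at each extreme. In RAB3A minus ZNF668, Nefm ranged from -0.13 (ZNF668 replicate 7) to 0.82 (ZNF668 replicate 9) and Rph3al from -0.18 (RAB3A replicate 2) to 0.020 (ZNF668 replicate 9). In BC74C minus ZNF668, Abcb1a ranged from -0.19 (ZNF668 replicate 6) to 0.29 (ZNF668 replicate 9), Cxcl10 from -0.24 (ZNF668 replicate 9) to 0.52 (BC74C replicate 3) and Podxl from -0.12 (ZNF668 replicate 6) to 0.26 (ZNF668 replicate 9). Rab3a ranged from -0.047 (ZNF668 replicate 7) to 0.47 (ZNF668 replicate 9), Slc32a1 from -0.43 (ZNF668 replicate 7) to 0.42 (BC74C replicate 6) and Sst from -0.68 (ZNF668 replicate 7) to 0.30 (BC74C replicate 9). Zfp668 ranged from -0.11 (BC74C replicate 4) to 0.061 (ZNF668 replicate 6). In RAB3A minus BC74C, Cd74 ranged from -0.56 (RAB3A replicate 5) to 0.79 (RAB3A replicate 3), Gad2 from -0.053 (BC74C replicate 1) to 0.71 (BC74C replicate 3) and H2-Aa from -0.59 (RAB3A replicate 5) to 0.65 (RAB3A replicate 3). Kdr ranged from -0.20 (RAB3A replicate 1) to 0.18 (RAB3A replicate 2), Nefm from -0.22 (BC74C replicate 1) to 0.33 (BC74C replicate 3) and Podxl from -0.13 (RAB3A replicate 2) to 0.017 (BC74C replicate 2). In HGG minus ependymoma, Bcl7c ranged from -0.27 (ZNF668 replicate 2) to 0.068 (BC74C replicate 7), Bub1b from -0.053 (ZNF668 replicate 5) to 0.88 (BC74C replicate 7) and Foxm1 from -0.19 (ZNF668 replicate 2) to 0.18 (BC74C replicate 7). Neurod6 ranged from -0.68 (BC74C replicate 7) to 1.08 (BC74C replicate 9), Ntsr2 from -0.063 (BC74C replicate 7) to 0.41 (ZNF668 replicate 8) and Rab3il1 from -0.074 (BC74C replicate 9) to 0.30 (BC74C replicate 7). Rims2 ranged from -0.35 (BC74C replicate 7) to 0.43 (BC74C replicate 9), S100b from -0.028 (BC74C replicate 9) to 0.55 (ZNF668 replicate 8) and Tbr1 from -1.22 (BC74C replicate 7) to 0.40 (BC74C replicate 9). In the difference of the HGG effect between class genes, Id4 ranged from -0.48 (ZNF668 replicate 8) to 1.62 (ZNF668 replicate 2), Iqcg from -0.93 (BC74C replicate 9) to 0.015 (BC74C replicate 7) and Neurod6 from -2.95 (BC74C replicate 7) to 1.27 (BC74C replicate 9). Rab3il1 ranged from -0.49 (BC74C replicate 9) to 0.40 (BC74C replicate 7), Slc17a7 from -0.64 (ZNF668 replicate 5) to 1.59 (BC74C replicate 9) and Sytl4 from -0.21 (ZNF668 replicate 2) to 0.16 (ZNF668 replicate 6). Vtn ranged from -0.56 (BC74C replicate 7) to 0.94 (BC74C replicate 9) and Zfp668 from -0.39 (ZNF668 replicate 6) to 0.050 (ZNF668 replicate 5).

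The difference of Bcl7c between BC74C and other tumours was 0.44 within elw (exact permutation p = 0.0924) and -0.29 at its second probe set. After quantile normalization it was 0.47 (exact permutation p = 0.0434) and among tumours labelled ependymoma 0.76 (exact permutation p = 0.0346). None of these p-values is adjusted. That of Zfp668 was -0.25 at its second probe set.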

Other observations

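The Hoxa genes, the relation of Hoxa5 to the Y-linked mean and the comparison of each tumour with the class gene means were chosen after the values were seen.

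Hoxa5 and Hoxa7, position genes of the hindbrain and spinal cord, varied widely between these cortical tumours. Whether their low values lie above background was not assessed. Hoxa5 averaged 7.96 ± 1.43 (SD, n = 9) in ZNF668, 6.73 ± 2.11 (SD, n = 9) in BC74C and 5.83 ± 1.87 (SD, n = 6) in RAB3A tumours, and Hoxa7 averaged 6.93 ± 1.31, 5.38 ± 1.68 and 4.91 ± 0.84 with the same n. Hoxa5 ranged from 3.66, below the dim filter, to 9.57, and Hoxa3 averaged 4.81, 4.23 and 3.97 in the same order of class genes. Against ZNF668 tumours Hoxa7 differed by -2.02 in RAB3A (SE 0.69, limma adjusted p = 0.479) and -1.55 in BC74C tumours (SE 0.62, limma adjusted p = 0.523), so neither passed. Hoxa5 followed the Y-linked mean across the 24 tumours (r = 0.80, permutation p = 1e-05, the smallest these permutations can give, adjusted 7e-05; rho = 0.77, permutation p = 5e-05, adjusted 0.00028). Without the 2 farthest tumours r was 0.80, within elw 0.79 and within mmr 0.89.

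The Y-linked mean ran opposite to Xist (r = -0.57, permutation p = 0.00308, adjusted 0.00431; rho = -0.65, permutation p = 0.0008, adjusted 0.0014). Without the 2 farthest tumours r was -0.43, within elw -0.67 and within mmr -0.92, and by class gene -0.75 in RAB3A, -0.27 in BC74C and -0.56 in ZNF668 tumours. The mature oligodendrocyte list rose with the neuron list (r = 0.62, permutation p = 0.00117, adjusted 0.00205; rho = 0.48, permutation p = 0.0202, adjusted 0.0202). Without the 2 farthest tumours r was 0.62, within elw 0.50 and within mmr 0.90, and by class gene -0.15 in RAB3A, 0.74 in BC74C and 0.81 in ZNF668 tumours.

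Several lists were not called in any comparison. Between RAB3A and ZNF668 tumours, then between BC74C and ZNF668 tumours, their mean differences were -0.02 and -0.07 for mature oligodendrocyte, 0.01 and -0.01 for neuronal progenitor, 0.13 and 0.17 for T and NK cell, 0.24 and 0.12 for choroid plexus and 0.37 and -0.16 for red blood cell genes (2 members). They were -0.07 and 0.08 for hypoxia and glycolysis, -0.38 and -0.07 for mesenchymal glioma, 0.0007 and 0.09 for NF-kappaB target, -0.07 and -0.02 for BAF chromatin remodelling and -0.12 and -0.04 for p53 target genes. Aldh1l1, a marker of astrocytes, was the only astrocyte gene to pass adjusted over the list alone between BC74C and ZNF668 tumours, at 2.45 (SE 0.56; limma adjusted p = 0.0606 over all genes).

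Each tumour was set against the means of the class genes over the 50 genes that best separated them among the other 23 tumours, and 18 of 24 were nearest to their own: 5 of 6 RAB3A, 6 of 9 BC74C and 7 of 9 ZNF668 tumours. Of 100 orders of the labels, the real one included, 1 gave as many (permutation p = 0.01, the smallest these can give); the highest other gave 14 and the median 7. RAB3A replicate 6 was nearest to ZNF668. BC74C replicates 3, 4 and 7 and ZNF668 replicates 5 and 9 were nearest to RAB3A. Their neuron list means were high, at 9.42 to 10.13, and that of RAB3A replicate 6 was 7.98. Against this, BC74C replicates 5 and 8, at 9.565 and 10.21, and RAB3A replicate 3, at 7.55, were nearest to their own class gene. How far nearness followed the neuron list rather than the class gene was not tested. Without RAB3A replicate 6 limma called 40 genes between RAB3A and ZNF668 and 46 between BC74C and ZNF668 tumours, with 21 shared, 1 higher and 20 lower in both.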
